A study of Mus musculus with 12 samples.

How the data were processed

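Quadriceps RNA of C57Bl/6J mice was measured on 12 mouse expression arrays, 3 per group, each hybridized with RNA pooled from 3 mice. The deposited values are signal intensities on a linear scale, made by the authors with MAS5 per their processing notes, whose version is not given in the sources used here. Leaving out the lowest and highest 2% of values, the mean of each array lay between 200.093 and 200.098, as global scaling to a common mean gives, and no value was at or below 0. The table held 22690 probe sets. Detection calls and raw array images were not used here. The signals of 27 bacterial control probe sets had a median of 4.88 and a 95th percentile of 23.5 over the arrays, which served as the background level.

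The values were log2-transformed as deposited, with no further scaling and no pseudocount. After 64 control probe sets were left out, 22626 remained, and the upper 60% by mean log2 signal over all arrays, 13575 probe sets with a mean signal above 28.4, were tested. Gene symbols came from the array annotation: 20393 probe sets had 1 symbol, 691 had several and 1606 had none, and 12512 of those tested had 1 symbol. Of those with 1 symbol, 20364 had a gene identifier in the RefSeq table, and 0 changed symbol through it.

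In R 4.3.3 with limma 3.58.1, a linear model with the 4 groups was fitted to all 12 arrays (8 residual degrees of freedom), with moderated variances that follow an intensity trend (median prior of 6.84 degrees of freedom). The contrasts were exercise, GW and the combination against vehicle, the combination against exercise and against GW, and the interaction, the drug effect in trained mice minus that in sedentary mice. All tests were two-sided, with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05 on the adjusted p. The number of arrays, 3 per group, limits the precision.

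Gene lists fixed in advance were tested with camera from limma, with a preset correlation between genes of 0.01, on 7940 genes with 1 probe set each (the one with the highest mean signal), adjusted over the lists of a comparison. Of 21 lists, 20 with at least 3 members tested were used: PPAR target genes, mitochondrial fatty acid oxidation, lipid synthesis, adipocyte (fat cell) markers, slow and fast fibre contractile genes, oxidative phosphorylation, the tricarboxylic acid cycle, glycolysis and glycogen, endothelial markers, extracellular matrix and fibroblast genes, macrophage markers, Schwann cell and nerve markers, denervation and regeneration, proteolysis and atrophy, immediate early and exercise-responsive genes, heat shock and unfolded protein genes, circadian clock genes, antioxidant genes and metallothioneins, and interferon response genes. The blood cell list, with 1 member tested, was left out. Calls were repeated with a correlation estimated from the data and with fry, which tests whether the genes of a list move on balance in one direction. Members past the threshold were counted over all probe sets tested and adjusted over the list alone.

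Genes were named by a rule set in advance. For each comparison with vehicle these were the 10 called probe sets with the largest increases and the 10 with the largest decreases, with 1 gene symbol and all 3 arrays of one group above all 3 of the other, and 5 of each for the other comparisons. Where fewer than 3 passed, the 5 genes with the smallest p were added as not passed. From each list up to 4 members were named per comparison, those past the threshold before those with the smallest p. Pdk4, Ucp3, Angptl4, Cpt1b, Fabp3, Scd1, Fasn, Ppard, Ppargc1a, Prkaa1, Prkaa2, Myh7, Myh4 and Cs were named always. Of these Cpt1b, Prkaa1 and Prkaa2 had no probe set with their symbol alone, and Ppard and Myh7 lay below the filter. Per-array signals of Adipoq, Scd1, Fasn, Fos, Hspa1b, Pdk4, Angptl4 and of the genes that stood apart in GW array 1 were chosen after their values were seen.

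The procedure was tested on simulated data with 22626 probe sets and the spread of these arrays, in 5 runs with 200 changed probe sets each. Of the changed probe sets, 29.1% were called at a 1.5-fold change, 60.2% at 2-fold and 84.6% at 3-fold, with 0 in the wrong direction. Of the calls 5.08% were false, and a comparison without changed probe sets gave 0 calls on average. A shifted list was called in all 5 runs and unchanged lists in 0. The simulated probe sets varied independently, while the estimated correlation was 0.811 for adipocyte markers. The runs therefore cannot show how often camera calls unchanged lists whose genes vary together. The shift, placed on the tricarboxylic acid cycle list, was also larger than the median changes of that list against vehicle.

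Alternatives were quantile and cyclic loess normalization, a pseudocount of 10.5 (the 20th percentile of all values), no filter, a filter at the upper 40%, moderation without a trend and with a robust prior, array weights, a fit of only the groups compared, array number as a block, 1 probe set per gene, an adjusted p under 0.1, an unadjusted p under 0.05 with at least a 1.5-fold change, and leaving out each array in turn. A per-array score of adipocyte markers as a covariate and the removal of arrays that stood apart were added later. Calls shared between comparisons were set beside the number that independent calls would share. Simulated unchanged groups gave 0 calls, so they provide no value for calls shared through the same vehicle arrays.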

Results

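Gene expression was measured in quadriceps muscle of C57Bl/6J mice on 12 oligonucleotide arrays that fell into 4 groups of 3. Sedentary mice received vehicle or GW1516, an agonist of the nuclear receptor PPARδ, at 5 mg/kg per day, and exercise-trained mice received vehicle or the same drug, in each case for 4 weeks. The groups are called vehicle, GW, exercise and combination here. Each array held RNA pooled from 3 mice, so each group stands for 9 mice and the p-values measure only the spread between pools. The median signal per array lay between 48.4 and 57.2, and the precision is limited by the number of arrays. The mean correlation of an array with the others of its group lay between 0.95 (GW array 1) and 0.968. With the arrays of other groups it lay between 0.951 and 0.963. GW array 1 (0.9496 against 0.9508) and GW array 2 (0.9571 against 0.9631) had a lower mean correlation within their group than with other groups. In all, 13575 probe sets were tested, and the median standard error of a log2 fold change was 0.21. Values are mean signals ± SD with n = 3 arrays, log2 fold changes are given ± SE, and adjusted p-values come from limma. The comparisons, the gene lists and the rule for naming genes were set before the data were examined.

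The comparison of GW with vehicle asked what the drug did in sedentary muscle. It raised genes that bring fatty acids into the cell and into the mitochondrion and break them down there. Acadl (Entrez gene 11363), a dehydrogenase that opens the oxidation of long-chain fatty acids, rose 2.53-fold, from a signal of 1118 ± 76.5 to 2826 ± 174 (log2 1.34 ± 0.10, adjusted p = 1.74e-05). Slc27a1 (Entrez gene 26457), a fatty acid transport protein, rose 2.88-fold, from 115 ± 17.3 to 330 ± 11.4 (log2 1.53 ± 0.15, adjusted p = 0.000181). Ucp3 (Entrez gene 22229), an uncoupling protein of the muscle mitochondrion, rose 2.66-fold in one probe set (log2 1.41 ± 0.13, adjusted p = 0.000119) and 2.26-fold in the other (0.000181). Mlycd, which removes the malonyl-CoA that holds back fatty acid entry, rose 1.80-fold, the fatty acid binding protein Fabp3 rose 1.77-fold, the carnitine carrier Slc25a20 rose 1.83-fold, and the thiolase Acaa2 rose 2.05-fold in one probe set and 1.60-fold in another, with a log2 fold change of 0.26 (adjusted p = 0.877) in the third. Fbp2, the muscle fructose bisphosphatase of gluconeogenesis, rose 2.31-fold (log2 1.21 ± 0.12, adjusted p = 0.000165).

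Among the genes that fell, Pfkfb3, whose product makes the activator of phosphofructokinase, fell by 1.40 ± 0.19 on the log2 scale in one probe set (adjusted p = 0.00529), while its other probe set had -0.08 (0.965). The stress-inducible gene Gadd45g fell by 1.19 ± 0.18 (adjusted p = 0.0112), and Dusp10, a phosphatase of stress-activated kinases, fell by 0.85 ± 0.14 in one probe set (adjusted p = 0.0246), with -0.90 (0.373) in the other. In total 10 probe sets of 8 genes were higher and 3 probe sets of 3 genes were lower. In all 13 the 3 GW arrays lay on one side of the 3 vehicle arrays, as 11% of all probe sets tested did, where chance gives 10%. At an unadjusted p under 0.05 there were 872 probe sets, where chance gives 678.8. The calls on Acadl, Slc27a1, Fbp2, Mlycd and Ucp3 stood in every alternative processing that tested them. Without an intensity trend all the other calls ended, Pfkfb3 included (0.138), except that on Acaa2 in the probe set with the smaller change. The Slc25a20 call ended when any 1 array but exercise array 3 was left out. This held for vehicle array 1 (adjusted p = 0.205), 2 (0.179) or 3 (0.0672) and for GW array 1 (0.17), 2 (0.0741) or 3 (0.0954). It also held for combination array 1 (0.073), 2 (0.0909) or 3 (0.0836) or exercise array 1 (0.0515) or 2 (0.0548). The Acaa2 call with the larger change ended without vehicle array 1 (adjusted p = 0.0996), vehicle array 3 (0.0666), GW array 1 (0.1) or GW array 2 (0.0969). The Fabp3 call ended without vehicle array 2 (0.0653). The Gadd45g call ended without vehicle array 2 (0.095), vehicle array 3 (0.0672), GW array 1 (0.0581) or GW array 2 (0.0529). The Dusp10 call ended without vehicle array 2 (0.179), vehicle array 3 (0.116), GW array 1 (0.0581), GW array 2 (0.0529) or GW array 3 (0.182).

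The list of mitochondrial fatty acid oxidation genes was shifted upward by GW. Of its 19 genes tested, 17 had a positive log2 fold change, 3 rose over all probe sets tested and 9 rose when adjusted over the list alone (median log2 0.24, camera adjusted p = 1.82e-17, adjusted p = 0.0133 with an estimated correlation). Among 16 PPAR target genes, 14 were positive, Ucp3 and Fabp3 rose over all probe sets, and 8 rose when adjusted over the list alone (median log2 0.56, camera adjusted p = 6.42e-13, adjusted p = 0.0267 with an estimated correlation). Pdk4, a kinase that restrains pyruvate oxidation, had a log2 fold change of 1.24 (adjusted p = 0.074), with GW array signals of 5330, 2710 and 2950. Angptl4, a secreted inhibitor of lipoprotein lipase, had a log2 fold change of 2.26 (adjusted p = 0.528), with GW signals of 304, 145 and 177. Upward shifts were also called for fast fibre contractile genes (camera adjusted p = 3.41e-05), oxidative phosphorylation (0.000104), heat shock genes (0.00119), the tricarboxylic acid cycle (0.00442), lipid synthesis (0.00905) and slow fibre contractile genes (0.0317). With an estimated correlation the same lists had adjusted p = 0.397, 0.202, 0.397, 0.116, 0.397 and 0.484. By fry the tricarboxylic acid cycle held (adjusted p = 0.0431), and the others of these did not (0.136 to 0.614). The slow fibre call rested on GW array 1, without which it had an adjusted p = 0.924 in the other direction. The heat shock call ended there as well (0.198). Without vehicle array 3 the slow fibre (0.408) and heat shock (0.0523) calls ended. Without GW array 2 the lipid synthesis call ended (0.0681). The fast fibre call ended without GW array 3 (0.0549) or with quantile normalization (0.322). GW array 1 also stood apart in Ankrd2, a stretch-responsive gene on the slow fibre list, with a signal of 2388 against 105 and 89.4 in the other GW arrays.

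**Figure D1:**
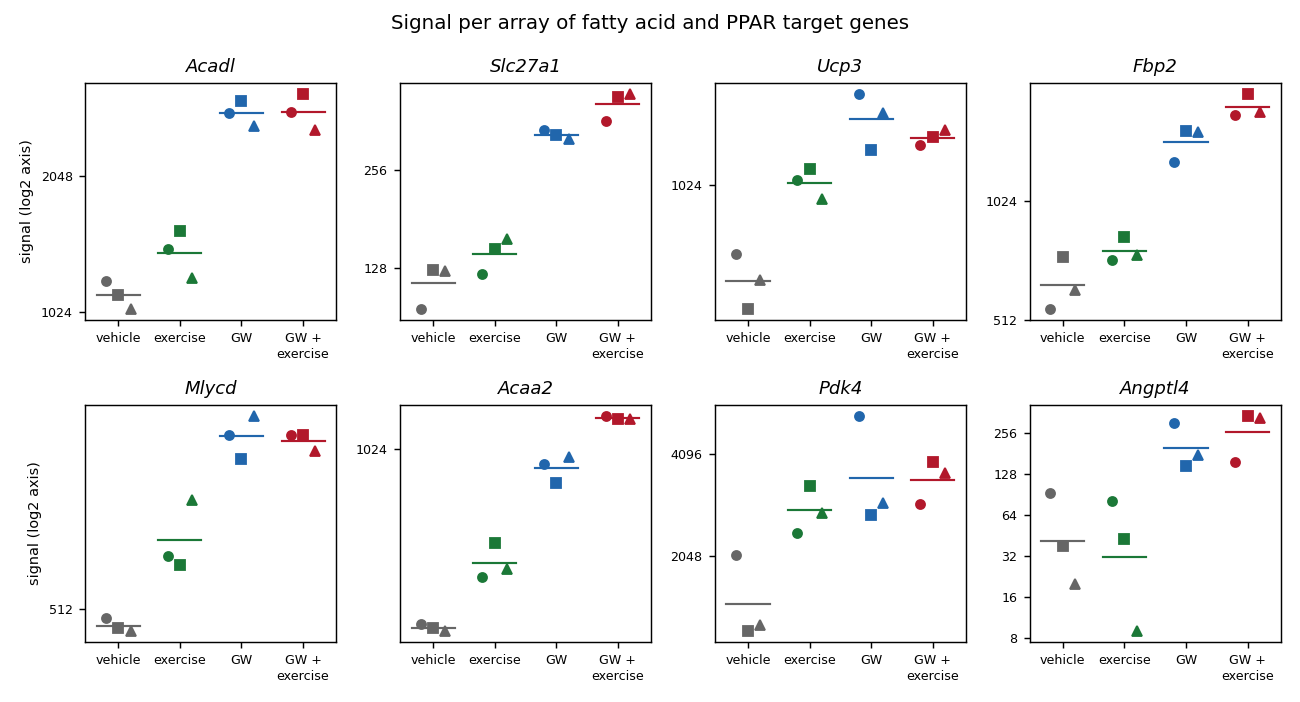
Signal of 8 genes in each array, on a log2 axis, by group; circle, square and triangle are arrays 1, 2 and 3 and the line is the geometric mean. Acadl, Slc27a1, Fbp2 and Ucp3 rose in GW and in the combination against vehicle, while Pdk4 and Angptl4 did not pass the threshold.

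The comparison of exercise with vehicle asked what training alone did. Egr1 (Entrez gene 13653), a transcription factor gene switched on quickly by many stimuli, rose 11.8-fold, from 74.0 ± 14.3 to 867 ± 71.8 (log2 3.57 ± 0.53, adjusted p = 0.0469). Kif1b (Entrez gene 16561), a motor protein that carries organelles along microtubules, fell by 0.62 ± 0.09 on the log2 scale, from 996 ± 34.9 to 649 ± 30.2 (adjusted p = 0.0469); its 6 other probe sets tested did not pass. Genes with the smallest p-values after these did not pass. Fos had signals of 50.6 ± 3.16 and 967 ± 140 (log2 4.25 ± 0.66, adjusted p = 0.053). Ucp3 in one probe set had a log2 fold change of 0.71 and Klf15, a regulator of amino acid breakdown, one of -0.97 (adjusted p = 0.0815 for both). Ttf1 and the collagen chaperone gene Serpinh1 had -1.97 and 1.14 (0.0874 for both), and 0.09 and 0.77 in their other probe sets. Of genes often measured as marks of training none passed. Citrate synthase, Cs, had log2 fold changes of -0.02 ± 0.07, 0.08 ± 0.07 and 0.18 ± 0.10 in its 3 probe sets, and the fast myosin gene Myh4 had 0.18 ± 0.07. The 5 probe sets of Ppargc1a lay between -0.37 ± 0.32 and 0.33 ± 0.26, estimates too wide to exclude a moderate change.

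These 2 calls were all that limma made, with 1417 probe sets at an unadjusted p under 0.05 (773 higher, 644 lower) where chance gives 678.8, and with the groups separated in 17.4% of probe sets where chance gives 10%. The count fell to 0 with quantile normalization, with cyclic loess, without an intensity trend and with a robust prior. It was also 0 without vehicle array 2 or 3, exercise array 1, 2 or 3, combination array 2 or GW array 3. It was 20 without combination array 1, 10 without GW array 1, 5 without GW array 2 and 4 without vehicle array 1. Egr1 and Kif1b were not called without vehicle array 1 (adjusted p = 0.0602 and 0.065), nor Kif1b without combination array 3 (0.061). With only the exercise and vehicle arrays in the fit, which leaves out the spread of the GW and combination arrays, the count was 33 and Fos passed (adjusted p = 2.98e-07). Over all alternatives the adjusted p of Egr1 lay between 2.12e-06 and 0.269 and that of Fos between 2.98e-07 and 0.304.

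The list of immediate early genes, which muscle activates in response to contraction and other stimuli, shifted upward with training. All 14 members tested were positive, Egr1 rose over all probe sets, and 9 rose when adjusted over the list alone (median log2 1.27, camera adjusted p = 1.02e-14, adjusted p = 0.125 with an estimated correlation). Heat shock genes moved with them: Hspa1b had a log2 fold change of 4.06, Hspa1a 3.14 and Dnajb1 2.32, none past the threshold over all probe sets. Of 14 members 6 rose when adjusted over the list alone (camera adjusted p = 4.59e-06, adjusted p = 0.146 with an estimated correlation). In single arrays Fos was at 900, 872 and 1130 in exercise and at 460, 92.5 and 39.2 in the combination. Hspa1b was at 1370, 1520 and 1600 in exercise and at 1940, 208 and 50.7 in the combination. The ratio of 3' to 5' signal of beta-actin was 0.778, 0.816 and 0.763 in the exercise arrays and 1.10, 0.918 and 0.838 in the vehicle arrays. That of Gapdh was 0.94, 0.896 and 0.917 in exercise and 0.89, 0.906 and 0.904 in vehicle.

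Muscle structure and energy lists were called as well. Fast fibre contractile genes had a median log2 fold change of 0.18 (camera adjusted p = 2.42e-09), with 7 of 14 members higher when adjusted over the list alone and Myh1 at 0.96, not past over all probe sets. Slow fibre genes had a median of 0.58 (0.00124), with myoglobin, Mb, at 1.07. Oxidative phosphorylation and glycolysis had medians of 0.11 and 0.17 (4.59e-06 for both), the tricarboxylic acid cycle 0.06 (0.0396), PPAR target genes 0.23 (0.000236) and fatty acid oxidation 0.09 (0.000475). Macrophage markers had a median of 0.36 (0.00562) and extracellular matrix genes 0.16 (0.0433). Proteolysis genes had a median of -0.15 (0.000913), with Klf15 and Foxo3 (log2 -1.01) among 4 members lower when adjusted over the list alone. With an estimated correlation none of the 12 lists called in this comparison held: adjusted p = 0.214 for slow fibre genes, 0.422 for macrophage markers, 0.522 for extracellular matrix and 0.146 for the remaining ones beside immediate early genes. By fry, immediate early genes, oxidative phosphorylation and glycolysis held (adjusted p = 0.0306 for each). So did fatty acid oxidation, fast fibre genes, the tricarboxylic acid cycle and proteolysis, just under the threshold (0.0497 for each). The others called here did not pass by fry (0.0746 to 0.465). The fast fibre and glycolysis calls also ended with quantile normalization (adjusted p = 0.218 and 0.0745). Without a filter on low signal those on the tricarboxylic acid cycle (0.0812) and extracellular matrix (0.0941) ended, the latter also with the score of fat cell markers in the fit (0.102). The tricarboxylic acid cycle call ended without vehicle array 3 (0.0974), exercise array 1 (0.0981) or exercise array 2 (0.107). The macrophage call ended without vehicle array 2 (0.0971), vehicle array 3 (0.0651) or exercise array 2 (0.107). The extracellular matrix call ended without vehicle array 3 (0.538), exercise array 2 (0.107), exercise array 3 (0.112) or GW array 2 (0.0505).

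**Figure D2:**
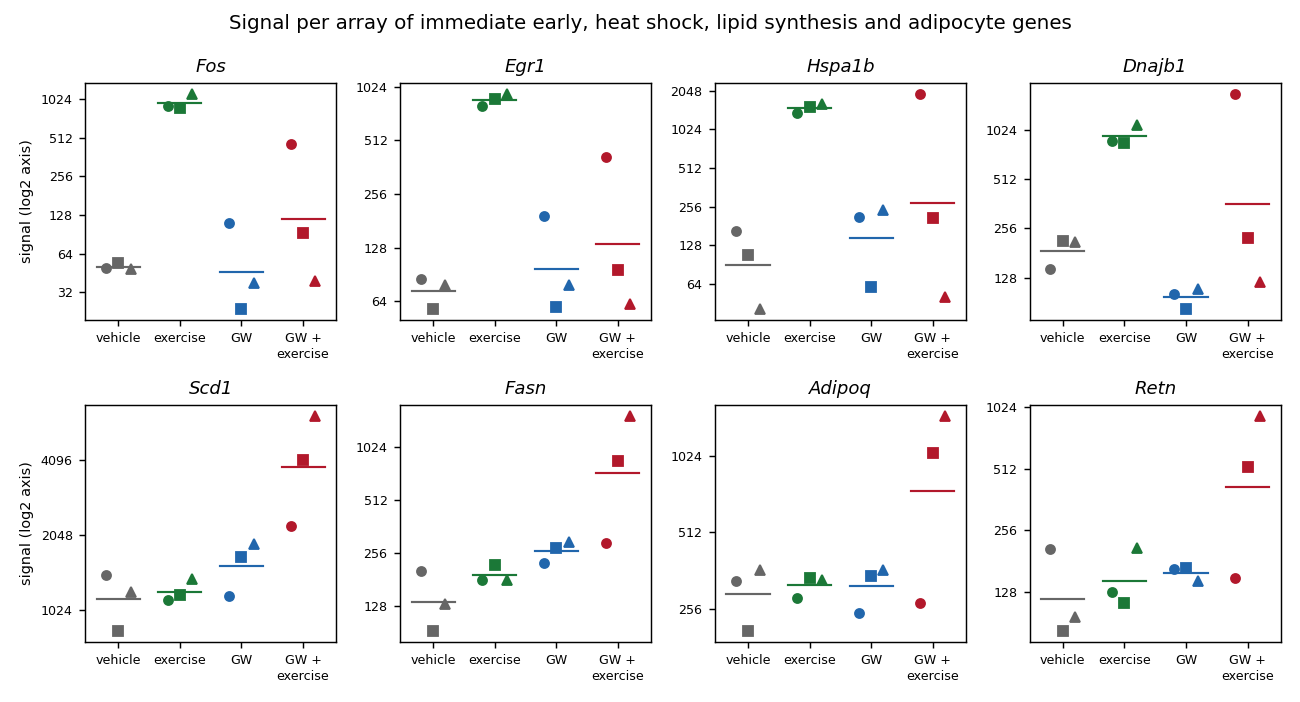
Signal per array, on a log2 axis, of genes of the immediate early, heat shock, fat cell and lipid synthesis lists, by group; circle, square and triangle are arrays 1, 2 and 3 and the line is the geometric mean. Fos and Hspa1b are high in the exercise arrays and in combination array 1, and Adipoq is higher in combination arrays 2 (1050) and 3 (1470) than in the other arrays (210 to 365).

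The comparison of the combination with vehicle asked what drug and training did together. The genes called higher in GW than in vehicle were called higher here too. Slc27a1 rose 3.60-fold (log2 1.85 ± 0.15, adjusted p = 1.63e-05) and Ucp3 2.94-fold (log2 1.56 ± 0.13, 1.63e-05). Fbp2 rose 2.83-fold (log2 1.5 ± 0.12, 1.36e-05) and Acadl 2.55-fold (log2 1.35 ± 0.10, 1.36e-05). Cpt1a, which loads long-chain fatty acids onto carnitine, rose 2.73-fold (log2 1.45 ± 0.23, adjusted p = 0.0181). In GW against vehicle it had not passed (log2 1.02, adjusted p = 0.28 by limma). Genes of fatty acid synthesis rose as well. The desaturase gene Scd1 (Entrez gene 20249) rose 5.67-fold in one probe set (log2 2.5 ± 0.37, adjusted p = 0.00827) and 3.40-fold in another (from 1158 ± 292 to 4181 ± 1980, 0.0181). The fatty acid synthase gene Fasn (Entrez gene 14104) rose 5.39-fold, from 141 ± 55.2 to 894 ± 628 (log2 2.43 ± 0.42, adjusted p = 0.0312). The acyl-CoA binding protein gene Dbi, the electron carrier gene Etfb and the noncoding RNA Malat1 also rose (log2 0.98, 0.55 and 1.06). Dbi and Malat1 did so in 1 probe set each, while the 3 other probe sets of Dbi had 0.45 to 0.52 and the 4 others of Malat1 0.00 to 0.29, none past the threshold. In 1 of 3 probe sets the annexin gene Anxa7 fell by 0.86 (adjusted p = 0.0499).

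In total 20 probe sets of 15 genes were higher and 1 was lower, all with the 3 arrays of each group separated, as in 16.8% of all probe sets where chance gives 10%. The count was 52 without combination array 1, 32 without vehicle array 3, 10 without vehicle array 2, 9 without combination array 2 and 10 without combination array 3. Scd1, in the probe set with the larger change, lost its call without vehicle array 2 (adjusted p = 0.0533), combination array 2 (0.086) or combination array 3 (0.0577), and its adjusted p ranged from 7.6e-05 to 0.412 over the alternatives. In the other probe set the call ended without the same arrays (0.109, 0.112 and 0.0768). Fasn lost its call without vehicle array 2 (0.166), vehicle array 3 (0.0596), exercise array 3 (0.059), combination array 2 (0.193), combination array 3 (0.105), GW array 2 (0.058) or GW array 3 (0.055), over a range of 0.000101 to 0.478. Cpt1a lost it without vehicle array 1 (0.0504), vehicle array 2 (0.102), combination array 2 (0.086) or combination array 3 (0.11). The Dbi call ended without vehicle array 2 (0.0945), combination array 2 (0.086) or combination array 3 (0.11). The Malat1 call ended without vehicle array 1 (0.105), vehicle array 2 (0.107), combination array 1 (0.0532), combination array 2 (0.086) or combination array 3 (0.0577). The Anxa7 call ended in 18 of 25 alternatives. Among them was the removal of vehicle array 1 (0.223) or 2 (0.195), exercise array 1 (0.0672), 2 (0.0689) or 3 (0.0726), combination array 1 (0.0814), 2 (0.171) or 3 (0.172) or GW array 3 (0.0712). With a score of fat cell markers per array in the fit, Fasn kept its call (log2 1.22, adjusted p = 0.0221). Scd1 kept it in one probe set (log2 0.99, 0.0303) and lost it in the other (log2 1.63, 0.0535). Cpt1a (log2 1.26, 0.172) and Dbi (log2 0.81, 0.195) lost theirs. Slc27a1, Fbp2 and Acadl stood in all alternatives.

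All 19 genes of fatty acid oxidation were positive against vehicle, 4 rose over all probe sets and 16 rose when adjusted over the list alone (median log2 0.32, camera adjusted p = 1.6e-27, adjusted p = 0.00282 with an estimated correlation). Of the PPAR target genes 3 rose over all probe sets and 11 of 16 rose when adjusted over the list alone (median log2 0.83, camera adjusted p = 2.21e-16, adjusted p = 0.0128 with an estimated correlation), with Pdk4 at log2 1.22 (adjusted p = 0.057) and Angptl4 at 2.65 (0.169). For lipid synthesis Scd1 and Fasn rose over all probe sets and 7 of 16 rose when adjusted over the list alone (median log2 0.44, camera adjusted p = 9.32e-10, adjusted p = 0.0354 with an estimated correlation). This call stood with the score of fat cell markers in the fit and without any single array (highest camera adjusted p of the latter 2.8e-07). The score was -0.531, 1.13 and 1.86 in the combination arrays and -0.802 to 0.0359 in the other arrays. Its slope in the fit thus rests mainly on differences among the combination arrays. This limits what any fit with the score can show about the combination. The tricarboxylic acid cycle had a median of 0.07 (camera adjusted p = 0.000567, adjusted p = 0.0448 with an estimated correlation). Fat cell markers moved with lipid synthesis: their median log2 fold change was 1.34, 0 of 8 passed over all probe sets by limma and 6 rose when adjusted over the list alone. Camera gave them an adjusted p = 2.27e-07, with adjusted p = 0.187 with an estimated correlation. Adipoq, the fat cell hormone adiponectin, had signals of 270, 1050 and 1470 in the combination arrays and 331, 210 and 365 in vehicle. In the same combination arrays Scd1 was at 2230, 4120 and 6190 and Fasn at 291, 847 and 1540. Calls on fast fibre genes (camera adjusted p = 2.39e-06), oxidative phosphorylation (2.39e-06), heat shock genes (2.33e-05) and immediate early genes (0.0364), all upward, had adjusted p = 0.279, 0.0863, 0.187 and 0.618 with an estimated correlation. By fry oxidative phosphorylation held (adjusted p = 0.0237), and the others of these did not (0.138 to 0.684). The immediate early call ended without vehicle array 1 (0.0643) or 2 (0.0825), and without combination array 1 the shift was downward (adjusted p = 0.797). The fast fibre call ended with quantile normalization (0.311). Without combination arrays 2 and 3, which leaves 1 array in that group, the call on fat cell markers ended, with a change of direction. It also ended with the score of these markers in the fit (0.677), as it must, since the score is made of the same genes.

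The comparison of the combination with exercise asked what the drug did in trained muscle. It raised Slc27a1 2.92-fold (log2 1.55 ± 0.15, adjusted p = 0.000206), Fbp2 (log2 1.21 ± 0.12, 0.000206) and Acadl (log2 1.03 ± 0.10, 0.000206). It also raised Cpt1a (log2 1.46 ± 0.23, 0.0169) and Scd1 in 1 probe set (log2 1.66 ± 0.28, 0.0266), with 1.47 (0.169) in the other. Wnt4, a secreted signalling protein, rose from 268 to 599 (log2 1.16 ± 0.14, adjusted p = 0.00161). Against vehicle Wnt4 had -0.65 (0.151) in exercise and 0.51 (0.201) in the combination. Klf15 rose from 193 to 358, beside 378 in vehicle (log2 0.89 ± 0.16, adjusted p = 0.0489). Among genes that fell, Odc1, which makes polyamines, fell by 1.2 ± 0.18 (adjusted p = 0.00948), and the immediate early phosphatase gene Dusp1 fell by 1.19 ± 0.20 (0.0264). The surface glycoprotein gene Cd24a fell by 1.14 ± 0.16 (0.00592), the nuclear import gene Kpna4 fell by 1.12 ± 0.17 (0.00948) in one probe set, with -0.23 (0.826) in the other, and the amino acid transporter gene Slc38a4 fell by 1.04 ± 0.19 (0.0392). The other probe sets of Odc1 (log2 -0.67 and -0.73), Cd24a (-0.37 and -0.40) and Slc38a4 (-0.45) did not pass. In exercise against vehicle the called probe sets of Odc1, Dusp1, Cd24a, Kpna4 and Slc38a4 had 0.42, 0.99, 0.67, 0.54 and 0.29. In the combination against vehicle they had -0.79, -0.20, -0.48, -0.58 and -0.74. None of these passed, so a fall below the vehicle level was not shown for these genes. Ucp3 rose in one probe set (log2 0.84 ± 0.13, adjusted p = 0.0126) and had 0.33 (0.414) in the other. Fabp3 and Pdk4 had log2 fold changes of 0.38 and 0.30 (adjusted p = 0.34 and 0.751). In the exercise arrays all 3 genes were above vehicle without passing the threshold.

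In total 13 probe sets were higher and 9 lower, each with the arrays of the groups separated, as in 15.8% of all probe sets where chance gives 10%. The count was 83 without combination array 1, 8 without combination array 2, 13 without exercise array 2 and 8 without exercise array 3. The Scd1 call ended without exercise array 1 (adjusted p = 0.0975), 2 (0.113) or 3 (0.0976) or combination array 2 (0.172) or 3 (0.108). The Cpt1a call ended without exercise array 1 (0.0704) or 2 (0.0866) or combination array 2 (0.0739) or 3 (0.11). The Ucp3 call ended without exercise array 1 (0.0636) or 3 (0.0757) or combination array 2 (0.0552). The Dusp1 call ended without exercise array 1 (0.0818), 2 (0.102) or 3 (0.15) or combination array 2 (0.189) or 3 (0.136). The Odc1 call ended without exercise array 2 (0.0579) or 3 (0.0837) or combination array 2 (0.0745). The Kpna4 call ended without exercise array 3 (0.0689) or combination array 2 (0.0739) or 3 (0.061), and the Cd24a call without exercise array 3 (0.0626). The Klf15 call ended in 14 of 26 alternatives. Among them was the removal of vehicle array 1 (0.0539), 2 (0.0673) or 3 (0.0566), exercise array 1 (0.168), 2 (0.138) or 3 (0.0976), combination array 1 (0.0651) or 2 (0.268) or GW array 3 (0.0835). The Slc38a4 call ended without vehicle array 2 (0.061), exercise array 1 (0.0932), 2 (0.152) or 3 (0.15), combination array 2 (0.226) or 3 (0.126) or GW array 2 (0.0607) or 3 (0.0598). Without both combination arrays 2 and 3, which leaves 1 array in that group, Slc27a1, Fbp2, Acadl and Wnt4 did not pass (0.105, 0.0833, 0.0833 and 0.127). Their log2 fold changes in that fit were 1.37, 1.14, 1.03 and 1.13. With the score of fat cell markers in the fit the count was 19, with 13 of the 22 calls kept, Scd1 among them. The calls on Cpt1a (0.126), Dusp1 (0.175), Kpna4 (0.0975), Slc38a4 (0.167) and Klf15 (0.138) ended.

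Fatty acid oxidation shifted upward in trained mice as well: 18 of 19 members were positive, 3 rose over all probe sets and 9 rose when adjusted over the list alone (median log2 0.20, camera adjusted p = 1.71e-16, adjusted p = 0.0161 with an estimated correlation). PPAR target genes had a median of 0.36 (camera adjusted p = 1.22e-06, adjusted p = 0.0927 with an estimated correlation) and lipid synthesis 0.62 (3.31e-09, adjusted p = 0.0627 with an estimated correlation), the latter with 10 of 16 members higher and 1 lower when adjusted over the list alone. Fat cell markers had a median of 1.10 (2.18e-05, adjusted p = 0.303 with an estimated correlation). Immediate early genes shifted downward against exercise, with a median of -0.71. The mean log2 signal of their members was 8.22 to 8.54 in the exercise arrays. It was 8.02 in combination array 1, near that range, and 7.33 and 6.69 in combination arrays 2 and 3, so the shift lay mainly in the latter. Dusp1 fell over all probe sets and 8 of 14 fell when adjusted over the list alone (4.94e-10, adjusted p = 0.0927 with an estimated correlation). Fos at -3.02 and Egr1 at -2.68 did not pass over all probe sets (adjusted p = 0.104 and 0.0664). Proteolysis genes had a median of 0.14 (0.0065), glycolysis -0.09 (0.0283) and macrophage markers -0.28 (0.0323), with adjusted p = 0.303, 0.384 and 0.559 with an estimated correlation. By fry lipid synthesis (adjusted p = 0.0378), PPAR target genes and immediate early genes (0.0475 for both) held. Fat cell markers, proteolysis, glycolysis and macrophage markers did not (0.0775 to 0.521). The proteolysis call ended without combination array 2 (0.0989). The glycolysis call ended without exercise array 2 (0.0789), exercise array 3 (0.0849) or combination array 3 (0.0715), and the macrophage call without exercise array 2 (0.271) or combination array 1 (0.736). Both calls ended with quantile normalization (0.135 and 0.0503) and without a filter on low signal (0.0781 and 0.0663). Without combination arrays 2 and 3 the calls on PPAR target genes (0.0637), proteolysis (0.0688) and glycolysis (0.266) ended, and fat cell markers (0.0445) changed direction. With the score of fat cell markers in the fit, the call on glycolysis ended (0.152) and that on lipid synthesis stood. The call on fat cell markers ended as well (0.709), as it must, since the score is made of the same genes.

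The comparison of the combination with GW asked what training added in mice on the drug. Limma called 0 probe sets, with 781 at an unadjusted p under 0.05 (375 higher, 406 lower) where chance gives 678.8 and the groups separated in 10.5% of probe sets where chance gives 10%. The smallest p-values belonged to Kpna4 (log2 -1.04, adjusted p = 0.218) and, all with an adjusted p = 0.287, Pfkfb3 (1.10), Scd1 (1.85), Mid1ip1 (-0.66) and Dusp10 (0.70). The other probe sets of Kpna4, Pfkfb3, Scd1 and Dusp10 had 0.03, 0.65, 1.32 and 0.04. Without combination array 1 the count was 35, and without GW array 2 it was 1. Camera called fat cell markers (median log2 1.09, adjusted p = 6.55e-07), lipid synthesis (0.35, 4.15e-06) and fatty acid oxidation (0.13, 7.06e-05), upward, with adjusted p = 0.384, 0.283 and 0.283 with an estimated correlation. All 3 calls ended without combination arrays 2 and 3, which leaves 1 array in that group (adjusted p = 0.133, 0.765 and 0.133), the fat cell markers with a change of direction. With the score of fat cell markers in the fit, the call on lipid synthesis ended (0.113). The call on fat cell markers ended as well (0.887), as it must, since the score is made of the same genes.

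The interaction asked whether the effect of the drug differed between trained and sedentary mice. Limma called 0 probe sets, with 922 at an unadjusted p under 0.05 (430 higher, 492 lower) where chance gives 678.8. The smallest adjusted p belonged to Kpna4 (log2 -1.58 ± 0.24, adjusted p = 0.102), followed by Kif1b (0.75) and Cd24a (-1.31), both at 0.158. The other probe set of Kpna4 had -0.60 (0.737), those of Kif1b -0.07 to 0.30 and those of Cd24a -0.46 and -0.32. For genes called in one setting and not in another the interaction was 1.21 for Scd1 (adjusted p = 0.707), 0.96 for Fasn (0.766), -3.09 for Egr1 (0.451), -1.31 for Dusp1 (0.404) and 0.97 for Klf15 (0.451), so a difference between settings was not shown for these genes. Scd1 had 0.81 (0.777) in its other probe set. For Ucp3 it was -0.58 (0.703) in the probe set called in both sedentary and trained mice and -0.84 (0.275) in the other. Without combination array 1 the count was 9, without GW array 2 it was 3 and without vehicle array 1 it was 1. Camera called 11 lists. Among them were immediate early (median log2 -0.77, adjusted p = 3.04e-07), fast fibre (-0.17, 5.28e-05), glycolysis (-0.10, 0.00269) and lipid synthesis (0.40, 0.0035). The others were slow fibre (-0.60, 0.0035), macrophage (-0.49, 0.0035), heat shock (-0.33, 0.0035), fat cell markers (0.96, 0.00551), oxidative phosphorylation (-0.09, 0.00613), denervation and regeneration (-0.18, 0.0212) and proteolysis (0.17, 0.0212). With an estimated correlation their adjusted p lay between 0.338 and 0.425. The slow fibre call ended without GW array 1 (0.0978), the macrophage call without combination array 1 (0.167), that on fat cell markers without combination array 3 (0.227) and that on oxidative phosphorylation without exercise array 2 (0.069). The denervation call ended without vehicle array 3 (0.0609), exercise array 2 (0.0897) or GW array 1 (0.285). The proteolysis call ended without vehicle array 3 (0.116), exercise array 1 (0.0593), combination array 2 (0.158) or GW array 3 (0.0848). With quantile normalization the calls on fast fibre genes (0.399), glycolysis (0.362), oxidative phosphorylation (0.1) and proteolysis (0.0557) ended. Without combination arrays 2 and 3 those on immediate early genes (0.0562), oxidative phosphorylation (0.0726), denervation (0.162) and proteolysis (0.147) ended. There lipid synthesis (0.915), heat shock genes (0.915) and fat cell markers (0.0221) changed direction. With the score of fat cell markers in the fit, the calls on lipid synthesis (0.138), heat shock genes (0.0911), denervation and proteolysis (0.0734 for both) ended. The call on fat cell markers ended as well (0.854), as it must, since the score is made of the same genes.

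The drug calls were shared between settings for part of the genes. All 10 probe sets higher in GW than in vehicle were also called higher in the combination than in vehicle, where independent calls would share 0.0147, though both comparisons use the same vehicle arrays. In the comparison of the combination with exercise, which shares no array with GW against vehicle, 5 of the 10 were called higher, where independent calls would share 0.00958. All 13 probe sets called in GW against vehicle had the same sign in the combination against exercise. Across all 13575 probe sets the effects of the drug in sedentary and in trained mice, which share no array, had a Pearson r of 0.0128 and a Spearman rho of 0.021, and the effects of exercise without and with the drug an r of 0.0527 and a rho of 0.0517. These correlations are across genes, which are not independent replicates. Their sign rested on single arrays. The r of the drug effects was 0.0891 without GW array 1, -0.0471 without GW array 2 and -0.0289 without vehicle array 1. That of the exercise effects was 0.154 without GW array 1, -0.0519 without GW array 2, and positive without any other single array.

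Of the 51 list calls in the 6 comparisons, 7 held with an estimated correlation: fatty acid oxidation and PPAR target genes in GW against vehicle, fatty acid oxidation, PPAR target genes, lipid synthesis and the tricarboxylic acid cycle in the combination against vehicle, and fatty acid oxidation in the combination against exercise. Endothelial markers, Schwann cell and nerve markers, circadian clock genes, antioxidant genes with metallothioneins, and interferon response genes were called by camera in none of the comparisons. Their lowest camera adjusted p-values were 0.148, 0.0901, 0.0917, 0.532 and 0.0615. By fry, Schwann cell and nerve markers passed in the combination against exercise (adjusted p = 0.0475), with all 4 members tested negative. Median, mean and test differed in sign only for lists that were not called. Their medians there were at most 0.042 from 0 on the log2 scale. For example, in GW against vehicle the endothelial list had a positive median (log2 0.01) and a negative mean (-0.07), and the antioxidant list a negative median (-0.01) and a positive mean (0.06). The blood cell list was not tested, since only 1 of its members passed the filter.

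**Figure D3:**
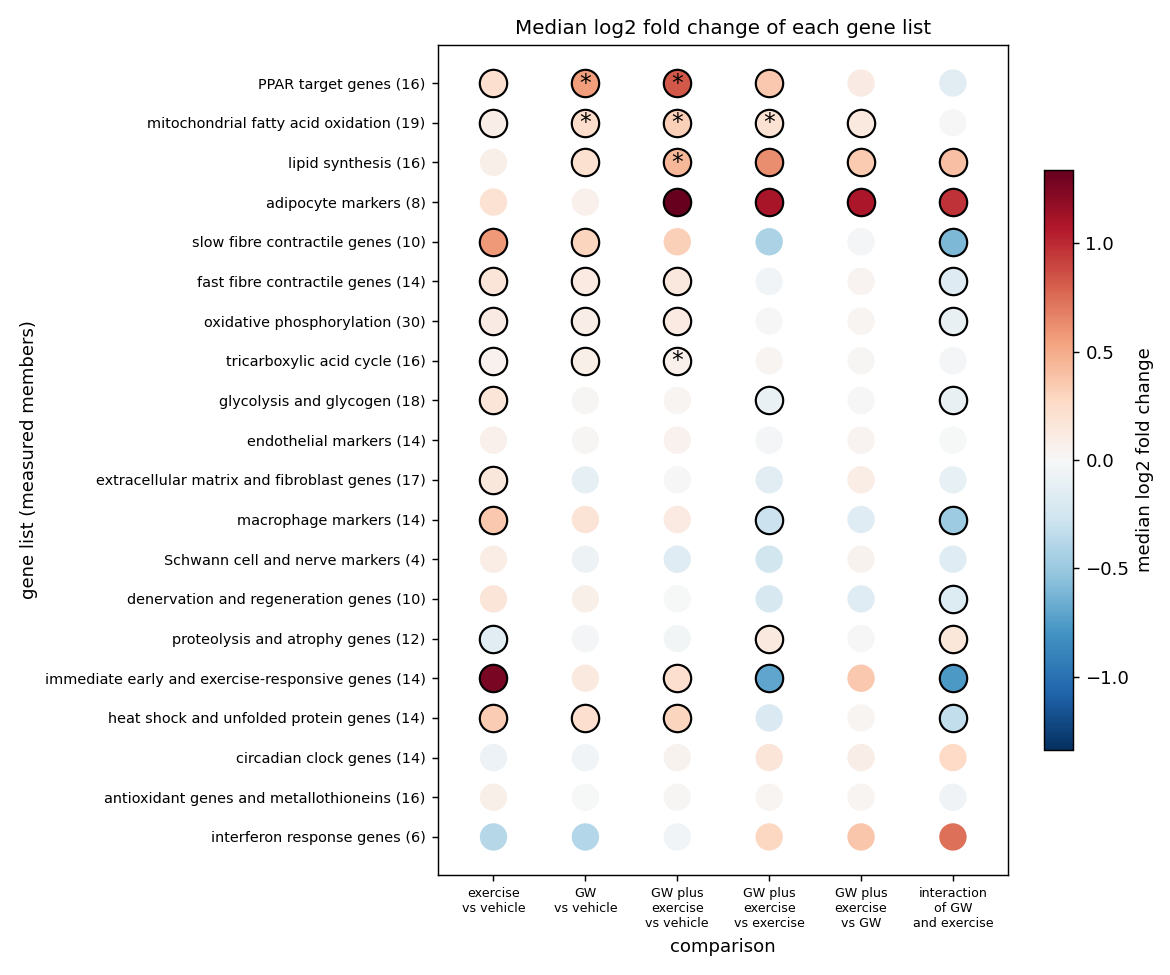
Median log2 fold change of 20 gene lists (vertical axis) in 6 comparisons (horizontal axis), shown by colour; an outline marks a camera adjusted p under 0.05 and an asterisk a call that held with an estimated correlation. Of the 51 outlined calls 7 carry an asterisk, 3 of them for fatty acid oxidation.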

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

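The tests of fat tissue RNA, of a mislabelled array, of degraded RNA, of the last bout of running and of slow muscle were chosen after the results were seen, and the counts over other splits of the arrays before.

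For 11 gene lists camera with the preset correlation called the interaction, the drug effect in trained mice minus that in sedentary mice. The median interaction on the log2 scale was 0.403 for lipid synthesis, 0.964 for adipocyte markers, -0.602 for slow fibre genes, -0.168 for fast fibre genes, -0.0948 for oxidative phosphorylation, -0.103 for glycolysis and glycogen, -0.486 for macrophage markers, -0.184 for denervation and regeneration genes, 0.166 for proteolysis and atrophy genes, -0.77 for immediate early genes and -0.332 for heat shock genes. None of the 11 held with an estimated correlation, so a drug effect that differs between trained and sedentary mice was not shown for them. Other drawn splits of the arrays gave as many list calls as the real one in 10 of 100 cases, the real one included, with up to 13. Some of these splits carry part of the drug effect into the interaction, since they exchange drug and vehicle labels. Their counts therefore do not measure chance alone, and they neither show nor exclude chance for the number of lists.

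Scd1 and Fasn were higher in the combination than in vehicle, together with fat cell markers, and mainly in combination arrays 2 and 3. RNA from fat tissue in these pools is a candidate explanation. With the adipocyte score of each array in the fit, the mean log2 difference of Scd1 and Fasn went from 2.1 ± 0.46 to 1.11 ± 0.169 (95% interval 0.71 to 1.51), while on the linear scale, with the Adipoq signal in the fit, the difference relative to the vehicle mean went from 3.97 ± 1.27 to 0.907 ± 0.433 (-0.116 to 1.93), so for this pair of genes fat tissue RNA and a response of the muscle cannot be told apart. An interval of 2 standard errors, used before the interval from the residual degrees of freedom, would have left the linear value above 0. For the other 14 lipid synthesis members the difference went from 0.542 to 0.238 (0.127 to 0.35) on the log2 scale and from 0.64 to 0.196 (0.0325 to 0.36) on the linear scale. Most of it went with the correction, and without Scd2 the linear value was 0.107 (-0.0573 to 0.272), so for these members fat tissue RNA and a response of the muscle cannot be told apart either. Before members were left out in turn, the part above 0 was read as evidence against fat tissue RNA as the whole cause. None of the 14 passed without the score (smallest adjusted p = 0.0988, for Acly), nor with it (0.0601, for Scd2), so the latter does not speak for fat tissue RNA. The members moved in both directions with the score. Scd2 went up in all its probe sets, from log2 1.19 to 1.70 in that with the largest change, and Gpam went from 1.31 to 1.60 in 1 probe set. Others went down, and some, such as Lpin1 (log2 -0.25), were below 0. A response of the muscle to drug and training stays open as untested.

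Immediate early and heat shock genes were high in the exercise arrays and in combination array 1. A mislabelled exercise array in place of combination array 1 is argued against by the genes that rose with GW, which were 0.626 (log2) higher there than in the highest exercise array. Degraded RNA is argued against by the 3' to 5' ratios of beta-actin and Gapdh, whose mean on the log2 scale differed by -0.0486 between these 4 arrays and the other 8. The upper end of its 95% interval, 0.0406, lay below the standard deviation of 0.0771 between the other arrays. Among these, GW array 1 showed part of the pattern. Its immediate early score was 7.53, and the mean log2 signal of its heat shock genes was 10. The Gapdh ratio alone lay above each vehicle array in exercise arrays 1 and 3, and an earlier form of the test, which took each ratio by itself, left degraded RNA open. A response to the last bout of running or to handling before collection may explain the pattern: 4 of 6 trained arrays had an immediate early score above all sedentary arrays. The highest sedentary score was that of GW array 1. Combination array 2, at 7.33, lay below it but above the other sedentary arrays (6.67 to 7.02). The sources used here state no time between the last run and collection, so this and a lasting effect of training stay open.

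Ankrd2, Csrp3 and the metallothioneins Mt1 and Mt2 were high in GW array 1, with signals of 2388, 1470, 3288 and 1988. Degraded RNA there is argued against by a beta-actin ratio of 0.801 and a Gapdh ratio of 0.883, both within the range of the other arrays. Slow muscle in that pool stays open. The 8 slow fibre members other than Ankrd2 and Csrp3 had a median log2 rise of 0.823 over the other GW arrays, against 4.62 for Ankrd2, but Myoz2 rose by 3.16, and Myl2 (43.8) and others had signals not far from the background of 23.5. An earlier form of this test left out Myoz2 and was read as evidence against slow muscle. The labels record no factor that differs between the pools of the group, so apart from slow muscle no biological explanation was tested.

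With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The number of probe sets called was 2 for exercise against vehicle (highest other split 0), 13 for GW against vehicle (1), 21 for the combination against vehicle (0), 22 against exercise (0) and, by limma, 0 against GW (0). Counting the real one, 1, 1, 1, 1 and 10 of the 10 splits gave as many. The number of lists called was 12 (highest other split 13), 8 (11), 9 (11), 8 (9) and 3 (11) in the same order, with 2, 3, 3, 4 and 10 of 10 splits giving as many. For the interaction, with 0 probe sets called by limma, all 100 drawn splits gave as many and the highest other gave 43. That split exchanges the GW and vehicle labels of sedentary mice, so it measures the drug effect shared by trained and sedentary mice, a structure of the samples. Splits that exchange only some of these labels can carry part of that effect.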

How the results depend on the processing

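The adipocyte score as a covariate, the fit without combination arrays 2 and 3 and the fit without GW array 1 and combination array 1 were chosen after seeing the data. Over all alternatives, 13554 values of named genes kept their side of the threshold, 249 lost and 200 gained a call, and 0 changed direction with a call. Values called neither in the main fit nor in the alternative counted as kept, whatever their direction, so these counts do not measure how stable the calls were. Of the list results, counted in the same way, 2129 kept their side of the threshold, 147 lost and 106 gained a call. A further 18 changed direction with a call in the main fit or in the alternative. Where no cause is given below, the cause was not tested. The correlation of drug effects, 0.0128, was -0.0111 with 1 probe set per gene, -0.0142 without a filter and -0.0471 to 0.0891 when single arrays were left out. That of exercise effects, 0.0527, was 0.148 with the adipocyte score and -0.0519 to 0.154 when single arrays were left out.

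For exercise against vehicle (2 probe sets called, 1417 at an unadjusted p under 0.05), limma gave 0 with quantile normalization, with cyclic loess, without a trend and with a robust prior. It gave 20 with array weights, 4 with 1 probe set per gene, 27 with the adipocyte score, 22 without combination arrays 2 and 3, 38 without GW array 1 and combination array 1, and 33 with only the groups compared. Leaving out single arrays gave 0 to 20.

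For GW against vehicle (13) the count was 7 without a trend, 20 with array weights and 7 with only the groups compared, and 10 to 18 when single arrays were left out. For the combination against vehicle (21) it was 7 without a trend, 94 with array weights, 12 with 1 probe set per gene, 69 without GW array 1 and combination array 1, and 9 to 52 when single arrays were left out. For the combination against exercise (22) it was 4 without a trend, 39 with array weights, 40 with only the groups compared, 0 by limma without combination arrays 2 and 3, which leaves 1 array in that group whose spread is taken to be that of the others, 117 without GW array 1 and combination array 1, and 8 to 83 when single arrays were left out.

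For the combination against GW (0 by limma, 781 at an unadjusted p under 0.05) it was 3 with the adipocyte score, 5 without combination arrays 2 and 3, 30 without GW array 1 and combination array 1, and 0 to 35 when single arrays were left out. For the interaction (0 by limma, 922 at an unadjusted p under 0.05) it was 1 with array weights, 1 with 1 probe set per gene, 6 without GW array 1 and combination array 1, and 0 to 9 when single arrays were left out.

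With the array numbers as a replicate block the combination against GW and the interaction each had 1 call in place of 0. Exercise against vehicle kept 1 of its 2 calls there, losing Kif1b (0.0895), GW against vehicle 11 of 13, and the combination 17 of 21 against vehicle and 18 of 22 against exercise. The deviations from the group means of same-number arrays of different groups had correlations of -0.0484 to 0.1 (mean 0.0131). For different numbers these were -0.0781 to 0.0613 (mean -0.00651). Yet 8 of the 12 arrays were closest to an array of their own number, so a weak effect shared by the numbers cannot be excluded. The labels do not say what the numbers mean, and they were not taken as pairs.

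An adjusted p under 0.1 gave 9 calls for exercise against vehicle, 43 for the combination against vehicle and 46 against exercise. An unadjusted p under 0.05 with at least a 1.5-fold change gave 559 for exercise, 353 for GW and 560 for the combination against vehicle, 506 for the combination against exercise, 344 against GW and 592 for the interaction.

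Of the 51 list calls, 7 held with an estimated correlation and fry made 20 calls, 19 of them among the 51. The remaining fry call was that on Schwann cell and nerve markers in the combination against exercise. The 10 calls shared by GW and the combination against vehicle were 149 with the unadjusted rule and 5 without combination arrays 2 and 3. Exercise and GW, with 0 shared, had 2 at an adjusted p under 0.1, 111 with the unadjusted rule, 2 with the adipocyte score and 2 without GW array 1 and combination array 1. Exercise and the combination, with 0 shared, had 3, 152, 9 and 5 in the same order, and 8 without combination arrays 2 and 3.

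Lists called in the main fit or in the alternative changed direction as follows, with their adjusted p there. Without GW array 1 and combination array 1, slow fibre genes in GW against vehicle (0.926), extracellular matrix (0.0277) and immediate early genes (0.861) in the combination against vehicle. When single arrays were left out these had 0.0014 to 0.924 (the latter without GW array 1), 0.0375 to 0.999 and 1.04e-05 to 0.797 (0.0375 and 0.797 without combination array 1). With the adipocyte score, macrophage markers in the combination against vehicle (0.013) and adipocyte markers in the combination against GW (0.887) and in the interaction (0.854). For adipocyte markers this outcome has no weight, since the score is made of the same genes. Without combination arrays 2 and 3, in the combination against vehicle, adipocyte markers (0.466) and macrophage markers (0.00762). There also, adipocyte markers (0.0445) and heat shock genes (0.0113) against exercise, adipocyte markers (0.133) and extracellular matrix (0.0016) against GW, and lipid synthesis (0.915), adipocyte markers (0.0221) and heat shock genes (0.915) in the interaction.

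Genes with a signal near the background of 23.5 have a wide spread on the log2 scale, which limits the calls on them, as for Angptl4.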

Other observations

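Other stress-responsive genes were also high in GW array 1. Atf3, a transcription factor gene induced by stress, had a signal of 374 there, a log2 rise of 4.51 over the other GW arrays, and the redox enzyme gene Srxn1 had 863, a rise of 1.91. The small heat shock protein genes Hspb1 and Cryab rose by 1.59 and 1.26. Mt1 was at 3288 in this array, where the highest signal in any other array was 1080, and Ankrd2 at 2388, where the highest other was 306. These genes were chosen after their values were seen.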
